A study of Daphnia magna with 107 samples.

How the data were processed

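RNA from whole Daphnia magna, a freshwater water flea used in toxicity tests, was measured on 1-colour Agilent arrays after 24 h of exposure. The 107 arrays fell into 25 groups and 9 exposures, each with its own control group. Per the labels' protocols, beakers held 60 animals, or 115 in the groundwater exposure, acetone carried the chemicals and was also given to controls, and the RNA was labelled with Cy3. The labels speak of quadruplicate beakers, while the groundwater groups and some of the mixture groups held 5 replicates, so which arrays shared a beaker is not known.

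The scanner files were made with Agilent Feature Extraction version 10.7.3.1, per the file headers, whereas the submitters' processing notes name version 9.5. Spot intensity was deposited as a processed signal that the scanner software had already corrected for background, per the file headers. The deposited value table held log2 values of the same arrays. Its scale and centring are not stated, and each of its columns correlated at r 0.995 to 0.999 with quantile-normalized, median-centred log2 signals of the same array over 14296 probes. The column medians of that table ran from -0.24 to 0.25, and 0 of its columns were left without a sample.

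Each array carried 14338 probes on 15208 spots, and 870 probes were printed on 2 spots. Control spots and the 3621 spots that the scanner software marked as outliers were left out, saturated spots were kept, and spots of 1 probe were averaged on the log2 scale. The value used was log2 of the processed signal minus the array's 75th percentile of it, so that each change is relative to that percentile. The median change over all tested probes ran from -0.23 with 26DNT and -0.23 with TNB to 0.13 with TNT. A probe was tested in an exposure when it was well above background on at least as many arrays as the smallest group held.

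Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with the package data.table (version 1.17.8) for reading. Groups that shared a control were fitted together, each single chemical was fitted with its control, and differences between chemicals were tested as interactions of exposure and chemical in a fit of both. P-values were adjusted by Benjamini-Hochberg within each result, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

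The depth of an array is its signal over background. The share of probes well above background ran from 10.0% to 94.3%, and the 75th percentile signal from 6.38 to 335. The number of arrays per group limits the precision. No 2 arrays were identical, and the highest correlation between 2 arrays was 0.974. The fit was tested on simulated data with 200 changed probes per result. It recovered 68.7% of changes of 2 log2 units for well 85 and 37.3% for mixture 7 (10491 and 8230 probes), and 14.9% for 26DNT, 17.9% for DNB and 14.9% for RDX (4723, 5400 and 6681 probes).

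The array's description column held no gene description for any probe, and 0 of the identifiers matched the table of 28335 genes that was at hand, so probes are given by their ID and no gene is named. The rule for naming was written before the data were examined. Among probes past the threshold, with every exposed array beyond the control mean, it took those with the largest rise and the largest fall, 1 probe per identifier, at most 2 each way where no gene names exist. For interactions it took those with the lowest p. Of the 3 probes higher with 24DNT, 1 is therefore not given. Lists of genes by description, written for 20 functions, could not be tested for the same reason. A search for words shared among sequences of the probe lists was tried and left out, because its correction covered only words already found repeatedly.

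Where a group was not well above background on every array, or was saturated, the fold is given as a bound. It sets the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. It allows for signal near background only, leaves out the spread between arrays, and can equal the fitted fold. Where arrays of the brighter group were also at background, it is not a strict minimum. Log2 changes in interactions and medians over sets of probes are as fitted, including where a group lay at background. Correlations of responses are across probes, which are not independent replicates. Planned correlations were tested by exact relabelling of the arrays of the first-named response (252 or 126 relabellings, 2-sided). For comparisons that share controls, 100 simulations of unchanged groups gave the correlation expected from sharing alone. List lookups used camera with a preset correlation of 0.01.

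The alternatives fixed before the data were examined were normexp background correction (offset 50) on mean and background signals, quantile normalization, no filter on dim probes, the slide as a block, the replicate number as a block, the deposited value table and the omission of each array. Slides were a fixed block for the groundwater, mixture and interaction results and a random block for single chemicals. No slide held more than 1 array of both groups of a comparison, so no comparison could be tested within 1 slide, and every exposure was scanned on 1 day (59 arrays on day 1 and 48 on day 2). Array brightness as a covariate, array weights and the omission of 8 arrays in doubt were added after the data were seen, as were the list lookups and the probe sets followed across exposures. An array was in doubt when under 20% of its probes were well above background or its mean correlation with its group was under 0.6. A further well that the study describes was not analysed here.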

Results

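Whole Daphnia magna were exposed for 24 h to munitions chemicals alone, in laboratory mixtures or in groundwater from field wells with munitions-contaminated groundwater, and their RNA was measured on 107 arrays. The 6 chemicals were the nitroaromatics TNT, 24DNT, 26DNT, DNB and TNB and the nitramine RDX, each given alone at 70% of 0.1 of its LC50. The single chemicals had 4 exposed and 4 control arrays each. Mixtures 1 to 4 and mixtures 5 to 8 had 5 control arrays per set, 5 arrays each for mixtures 1 and 5, and 4 for each other mixture. Groundwater had 5 arrays for each of well 85, well 108 and the control. Values below are log2 signal minus the array's 75th percentile, and a change is the exposed mean minus the control mean.

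The depth of the arrays differed between exposures. On average 66.9% ± 13.1 (SD, n = 5) of probes were well above background in the groundwater controls, and 59.9% ± 8.29 (SD, n = 5) in well 85. The mixture 7 arrays had 28.3% ± 5.42 (SD, n = 4) and the mixture 8 arrays 27.2% ± 16.1 (SD, n = 4), against 50.4% ± 16.5 (SD, n = 5) in their controls. The log2 of the 75th percentile signal was 4.04 ± 0.42 in mixture 7 (SD, n = 4) and 5.69 ± 1.12 in the controls of mixtures 5 to 8 (SD, n = 5).

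The groundwater comparison asked which transcripts respond to water that already holds a field mixture. Probe DM11208P3 showed the largest rise in well 85, from -0.63 ± 0.98 in the control to 5.43 ± 0.32 (SD, n = 5 each), a 66.6-fold rise. The same probe rose by 3.95 in well 108, to 3.32 ± 0.16 (SD, n = 5), or 15.5-fold. DM05883P1 rose 45.4-fold in well 85 as fitted (95% interval 4.10 to 6.91 log2 units), and 3 of its 5 control arrays measured it. Its bound equalled the fitted fold. DM04072P3 fell by 3.05 in well 85, 8.28-fold, and DM12419P1 at least 3.27-fold, with 1 of 5 well 85 arrays measuring it. In well 108, DM04155P3 rose 8.29-fold, DM06726P2 fell 2.66-fold, and DM03029P4 fell at least 1.97-fold with 0 of 5 exposed arrays measuring it. The direction of DM03029P4 reversed under normexp background correction. With limma, well 85 changed 95 probes upward and 60 downward of 10491 tested, and well 108 changed 7 upward and 2 downward. The adjusted p of DM11208P3 was 5.89e-07 in well 85 and 0.000236 in well 108, and all 5 exposed arrays lay above the control mean in both. With slide as a block, 32 probes passed for well 85 and 0 for well 108. Normexp background correction left 10 higher and 18 lower for well 85 and 0 for well 108, and array weights gave 256 higher and 295 lower for well 85.

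The wells were also compared directly. DM12433P1 was 3.04-fold higher in well 108 than in well 85. DM08460P1 was at least 1.12-fold higher, with 4 of 5 well 108 and 0 of 5 well 85 arrays measuring it. DM14845P1 was 4.66-fold lower in well 108, at 0.48 ± 0.23 against 2.70 ± 0.11 (SD, n = 5 each). DM10376P2 was at least 12.5-fold lower in well 108, where 0 of 5 arrays measured it. In all, 5 probes were higher and 19 lower in well 108 at adjusted p under 0.05 with limma, and 0 passed with slide as a block. All 7 probes that rose in well 108 also rose in well 85, and both that fell also fell, where independent lists of those sizes would share 0.0634 and 0.0114. The responses correlated across probes at r 0.37, and unchanged groups simulated against the same 5 controls gave 0.50. Their covariance was 0.124 against a simulated 0.124, and r was 0.01 on average when the controls were divided between the wells.

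Mixtures 1 to 4 combined the chemicals at concentrations set in the laboratory, with TNT at 0.972 to 1.061 mg/L in each. DM11208P3 rose at least 14.2-fold in mixture 4 (TNT with TNB), where all 4 arrays measured it, and at least 10.2-fold in mixture 1 (all 6 chemicals), where 4 of 5 did. Its changes in mixtures 2 and 3 were 2.51 and 3.22 as fitted, with 4 of 5 control arrays measuring it, and did not pass. DM00150P1 rose at least 2.72-fold in mixture 1, with 2 of 5 exposed and 0 of 5 control arrays measuring it, and DM08172P1 fell at least 2.44-fold, with 4 of 5 exposed arrays measuring it. DM04077P2 rose 5.36-fold in mixture 4, DM10043P1 fell at least 14.8-fold with 2 of 4 exposed arrays measuring it, and DM08406P3 fell at least 5.99-fold with 0 of 4. In mixture 2 (TNT, DNB and RDX), DM11981P2 alone passed, at least 3.63-fold higher, with 2 of 5 control arrays measuring it. Of 10555 probes tested with limma, 9 rose and 1 fell with mixture 1, 1 rose with mixture 2, and 8 rose and 4 fell with mixture 4. With mixture 3 (TNT and 24DNT), limma called 0 probes, and 382 lay under an unadjusted p of 0.05, where chance gives 528. Among the 4 mixtures limma called 0 probes as different, with 465 under an unadjusted p of 0.05. The calls for mixtures 1, 2 and 4 each fell to 0 when 1 or more single arrays were left out.

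Mixtures 5 to 8 were made to stand for field groundwater. DM02535P1 rose 24.2-fold in mixture 7 and 21.0-fold in mixture 8, to 4.49 ± 0.50 and 4.29 ± 0.30 (SD, n = 4 each) from -0.10 ± 0.32 in the control (SD, n = 5). It also rose by 3.03 in mixture 5, and its rise of 2.82 in mixture 6 did not pass. In mixture 7, DM03673P1 rose at least 9.54-fold, with 3 of 4 exposed and 1 of 5 control arrays measuring it. DM06997P1 fell at least 40.3-fold and DM09663P3 at least 22.1-fold in mixture 7, where 0 and 1 of 4 exposed arrays measured them. In mixture 8, DM06742P2 rose at least 18.7-fold with 0 of 5 control arrays measuring it. DM04338P2 fell there by at least 4.64 log2 units with 2 of 4 exposed arrays measuring it. DM04369P3 fell 51.8-fold there as fitted (95% interval -8.51 to -2.88 log2 units), with 1 control array saturated. Its control level was 7.69 ± 2.99 (SD, n = 5), and control replicate 4 lay at 2.45, near the mixture 8 mean of 1.99. Its bound equalled the fitted fold and leaves out this spread, so 51.8-fold is not a firm minimum. DM07443P3 and DM12447P3 fell at least 28.2-fold and 21.2-fold in mixture 5, each with 4 exposed arrays measuring it. DM02984P3 rose at least 5.21-fold in mixture 5, measured on 4 of 5 control arrays. DM03677P3 rose 2.78-fold there by the same bound, with 2 of 5 exposed and 2 of 5 control arrays measuring it, so this is not a firm minimum.

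Of 8230 probes tested with limma, mixture 7 changed 212 upward and 408 downward, mixture 8 changed 67 upward and 229 downward, and mixture 5 changed 5 upward and 50 downward. Normexp background correction left 3, 0 and 0 of mixtures 7, 8 and 5, and slide as a block gave 183, 564 and 1. The normexp offset of 50 lay above the 75th percentile signal of every mixture 7 and 8 array (highest 20.2 and 25.6), which shrinks log2 changes. The mixture 5 count ran from 0 to 388 when single arrays were left out. The adjusted p of DM02535P1 was 0.00104 in mixture 7 and 0.00268 in mixture 8, and all 4 exposed arrays lay above the control mean in both. With mixture 6 limma called 0 probes, with 784 under an unadjusted p of 0.05, and among mixtures 5 to 8 it called 0 as different, with 531. The responses to these mixtures correlated across probes at r 0.61 to 0.85, against 0.45 to 0.47 for simulated unchanged groups, and at 0.34 to 0.67 on average with the controls divided. Their covariances were 0.458 to 1.17 against a simulated 0.193 to 0.194. Mixtures 7 and 8 shared 189 lower and 37 higher probes, where independent lists would share 11.4 and 1.73. Within the groups of this set, dimmer arrays tended to lie farther along the response, with exceptions in mixtures 6 and 7. Over its 22 arrays, the signed mean of the 620 mixture 7 probes correlated with brightness within the groups at r -0.82 (permutation p 0.00042), and 13 probes passed for mixture 7 and 12 for mixture 8 with brightness as a covariate. Most of the change stayed in that fit, with a median over the called probes of 1.76 against 2.43 for mixture 7 and 1.98 against 2.68 for mixture 8.

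**Figure D1:**
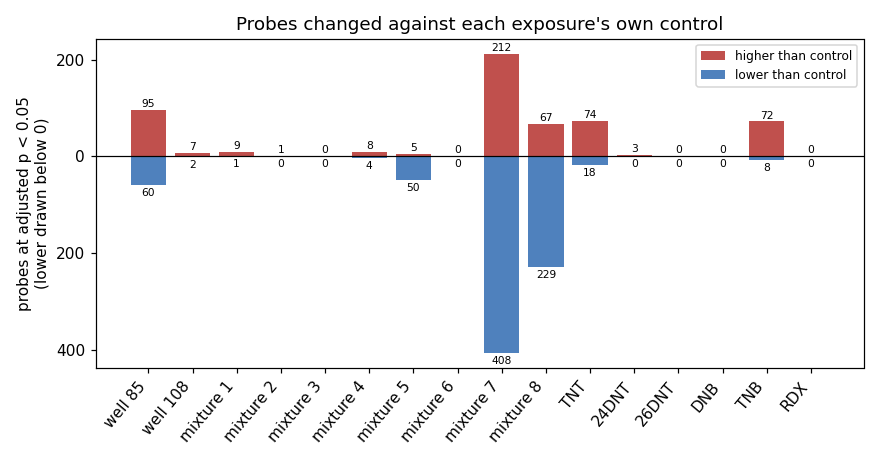
Number of probes past the threshold in each comparison with control, higher counts drawn upward and lower counts downward. Mixture 7 had 212 higher and 408 lower, and well 85 had 95 higher and 60 lower.

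**Figure D2:**
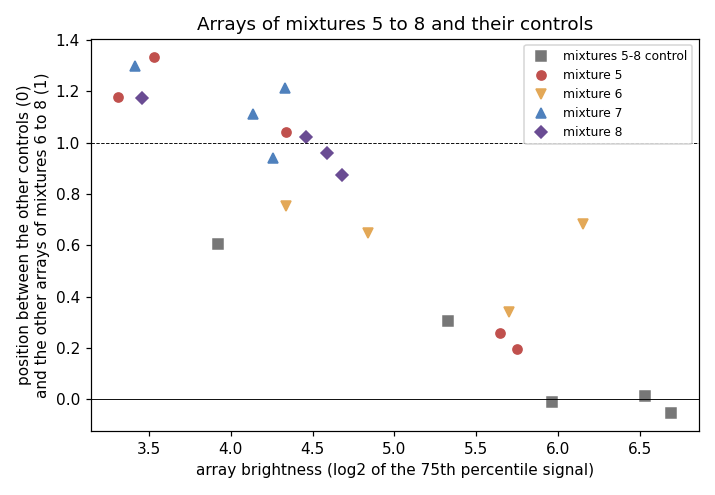
Position of each array of mixtures 5 to 8 on an axis from the mean of the other controls (0) to the mean of the other arrays of mixtures 6 to 8 (1), against the log2 of its 75th percentile signal. Control replicate 4, the dimmest control, lies at 0.61, and mixture 5 replicates 2 and 4, the brightest of mixture 5, lie at 0.26 and 0.20.

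TNT alone, at 0.498 mg/L, raised DM11495P2 at least 287-fold, the largest bound of any comparison with control. Its mean was 5.57 ± 3.14 in the exposed arrays (SD, n = 4), and 2 of 4 control arrays measured it. DM12463P3 rose at least 24.5-fold, with 2 of 4 control arrays measuring it. DM13898P4 fell 17.2-fold, and DM02069P3 fell at least 8.08-fold with 1 of 4 exposed arrays measuring it. Limma called 74 probes higher and 18 lower of 10418, and the adjusted p of DM12463P3 was 0.0362 with all 4 exposed arrays above the control mean. The count ran from 0 to 443 when single arrays were left out and was 0 with the replicate number as a block.

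TNB alone, at 0.386 mg/L, raised DM12902P2 158-fold, from -1.36 ± 0.55 to 5.94 ± 1.45 (SD, n = 4 each). DM06036P1 rose at least 61.9-fold with 1 of 4 control arrays measuring it. DM03044P2 fell 9.27-fold, and DM05651P1 fell at least 7.24-fold with 1 of 4 exposed arrays measuring it. DM12902P2 also rose by 3.08 with TNT, and its control level was 2.10 there. Of 7949 probes tested, 72 were higher and 8 lower with TNB, and DM12902P2 had an adjusted p of 0.00229 with limma. The count was 19 to 98 when single arrays were left out. Under normexp background correction 1 probe was higher and 3 lower, and DM12902P2 did not pass (adjusted p 0.078).

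TNT and TNB differ by a methyl group, and their comparison asked whether their responses overlap. In this and the other pairs of chemicals, doses in mg/L and control groups also differed. A difference in response therefore cannot be assigned to structure alone. Both raised DM12902P2, DM12463P3 and DM06036P1, among 20 probes in all, where independent lists of 51 and 69 among 7647 probes tested in both would share 0.460. Fisher's exact test over probes, which are not independent, gave an adjusted p of 2.96e-27. The overlap was 22 with quantile normalization, 24 with the deposited value table, 30 with slide as a block and 29 with array weights. It was 1 under normexp background correction and 0 without the dim filter, with replicate number as a block and with brightness as a covariate. Other probes differed between them as reported. DM06972P1 and DM11242P3, called as more positive with TNT, were measured on all 4 TNT exposed arrays and on 0 of 8 arrays of the TNB exposure, so no TNB response stands against the rise with TNT. The same held for 3 of the 77 calls in all. DM00848P1 changed by -2.03 with TNT and 3.83 with TNB, and DM04059P2 by -1.24 and 2.77. The sequences of these last 2 probes look like ribosomal RNA, possibly of another organism, and whether they measure Daphnia RNA was not tested. The interaction test in limma called 77 of 11584 probes, 45 more positive with TNT and 32 more positive with TNB, and these 4 had an adjusted p of 0.0193. Slide as a block and replicate number as a block each left 0 calls, and single omissions gave 0 to 212. The interval of a difference had a median 95% half-width of 1.71, and in simulated data the test recovered 2.99% of differences of 2 log2 units and 15.2% of 3, so most differences of that size would be missed.

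24DNT at 1.586 mg/L raised DM02749P1 51.6-fold, from 1.36 ± 0.49 to 7.05 ± 0.96, and DM08108P3 26.5-fold, from 1.57 ± 0.62 to 6.29 ± 1.15 (SD, n = 4 each). In the controls of the other exposures DM02749P1 lay at 4.88 with RDX and between 7.06 and 8.49 elsewhere, and DM08108P3 at 4.98 with RDX and between 7.31 and 8.66 elsewhere. The contrast in both probes therefore came with 24DNT controls that lay below every other control group. Limma called 3 of 8261 probes for 24DNT, with an adjusted p of 0.00905 for DM02749P1, which did not pass in 4 of 8 single omissions. The count ran from 0 to 8 in these omissions and was 11 higher and 59 lower under normexp background correction. Chance was not excluded, since 2 of 35 splits of the arrays gave as many.

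**Figure D3:**
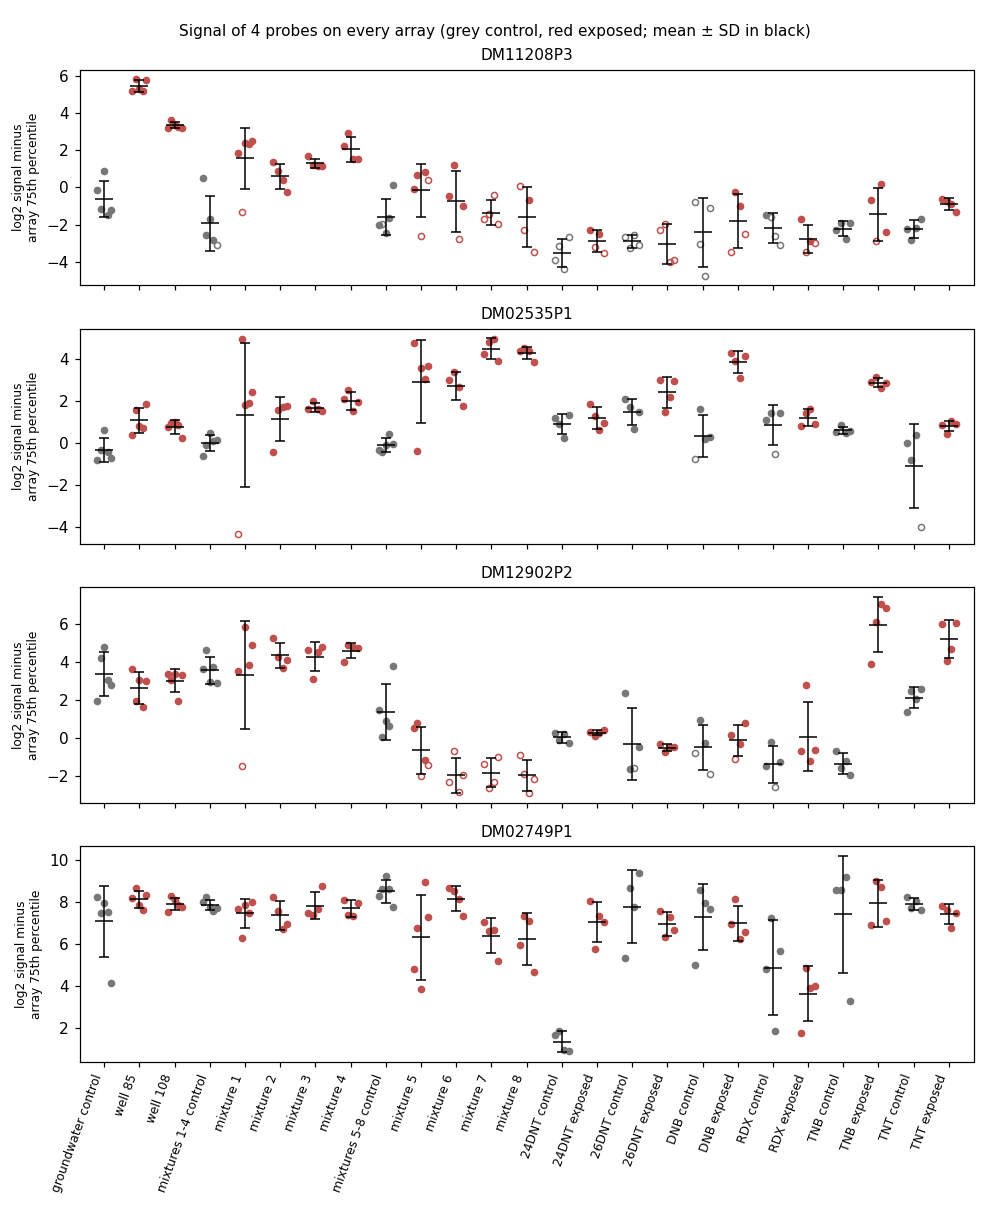
Log2 signal minus the array's 75th percentile for 4 probes on every array, grey for control and red for exposed, open where the probe was not well above background, with mean and SD in black. DM02749P1 lies at 1.36 in the 24DNT controls and above 4 in the mean of every other control group.

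For 26DNT, DNB and RDX limma called 0 probes. At an unadjusted p under 0.05 there were 225 of 4723 for 26DNT, 745 of 5400 for DNB and 215 of 6681 for RDX, where chance gives 236, 270 and 334. DM02535P1 changed by 3.55 with DNB as fitted, where DNB control replicate 1 did not measure it, and this did not pass (adjusted p 0.196, limma). In simulated data of these 3 comparisons the fit recovered 14.9% to 17.9% of changes of 2 log2 units.

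The isomers 24DNT and 26DNT were compared for whether the place of the nitro groups matters. DM02749P1 changed by 5.69 with 24DNT and -0.83 with 26DNT, and the responses of DM04265P3 differed by 5.70, and limma called 3 probes as different, all more positive with 24DNT. For DM04265P3, 0 of 4 24DNT controls and 1 of 4 26DNT exposed arrays measured it, and the DM02749P1 contrast rests on the low 24DNT controls. Slide as a block and replicate number as a block each left 0 calls, and single omissions gave 0 to 13. DNB and TNB, which differ by 1 nitro group and were given at 9.51 and 0.386 mg/L, gave 58 called probes of 9298. DM03044P2 fell by 3.21 with TNB and changed by 0.54 with DNB, and DM11444P4 changed by 2.56 with DNB and -1.16 with TNB. DM04058P1 changed by 5.09 with TNB and -2.81 with DNB, and DM12113P3 by 5.35 and -1.39 (adjusted p 0.000308 and 0.000814, limma), where 0 of 4 DNB exposed arrays measured either probe. In 6 of the 58 calls 0 of the 8 DNB arrays measured the probe. The calls were 6 more positive with DNB and 52 more positive with TNB. The count was 27 with slide as a block and 2 under normexp. Of the 80 TNB probes, 34 were tested with DNB, and 19 of those moved in the same direction there.

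TNT differed from 24DNT in 301 of 11804 probes, 227 more positive with TNT and 74 more positive with 24DNT, but in 3 with slide as a block and 10 with replicate number as a block. DM01229P3 changed by 2.08 with TNT and -2.50 with 24DNT, and DM01902P1 by 3.89 and -1.89. DM02749P1 changed by -0.48 with TNT and 5.69 with 24DNT, and DM07643P3 by -1.96 and 2.51 (adjusted p 0.000533 and 0.00241, limma). For DM02749P1 this contrast too rests on the low 24DNT controls. In 9 of the 301 calls 0 of the 24DNT arrays measured the probe. TNT differed from 26DNT in 23 of 11211 probes, all more positive with TNT. That count was 0 with slide or replicate number as a block, with quantile normalization, with the deposited value table and without the dim filter, and single omissions gave 0 to 57. In 7 of the 23 calls 0 of the 26DNT arrays measured the probe. Among the 23, DM06840P2 changed by 2.43 with TNT and -2.15 with 26DNT, and DM01902P1 by 3.89 and -1.02 (adjusted p 0.0392, limma).

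Whether laboratory mixtures or sums of single chemicals stand for a complex exposure was tested with 4 planned correlations of responses across probes. Well 85 was correlated with each of mixtures 5 to 8, and the coefficients were averaged. Which of these mixtures stands for which well is not given. The average was Pearson's r 0.06 and Spearman's rho 0.04 over 7706 probes (exact p 0.492, adjusted 0.656). The same average for well 108 was r 0.13 and rho 0.14 (exact p 0.222, adjusted 0.444). With the mixtures taken singly, r ran from 0.02 to 0.13 for well 85 and from 0.08 to 0.18 for well 108. Mixture 3 correlated with the sum of the TNT and 24DNT responses at r 0.00063 and rho 0.05 over 7761 probes (exact p 0.992, adjusted 0.992). Mixture 1 correlated with the sum of the 6 single responses at r 0.26 and rho 0.27 over 4104 probes (exact p 0.0873, adjusted 0.349). The doses did not match. TNT, TNB, DNB and RDX were given alone at 0.498, 0.386, 9.51 and 29.8 mg/L, against 1, 0.67, 1.107 and 0.334 in mixture 1. 24DNT (1.586 and 1.245) and 26DNT (1.152 and 1.13) were closer, and mixture 3 held 0.999 mg/L TNT and 1.242 mg/L 24DNT. These sums therefore do not show whether responses add up at equal doses. Under normexp background correction, for which no p was computed, r was 0.53 for well 85, 0.50 for well 108 and 0.56 for mixture 1. Its offset of 50 lay above the 75th percentile signal of every array of mixture 7, mixture 8 and 26DNT exposed (highest 20.2, 25.6 and 34.5). This shrinks log2 changes on dim arrays, and whether it raised r was not tested. None of the 4 passed as planned, and the probes are not independent replicates. The probes called in mixtures 7 and 8 also followed array brightness within groups. A low r therefore does not settle whether mixtures 5 to 8 stand for the wells.

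**Figure D4:**
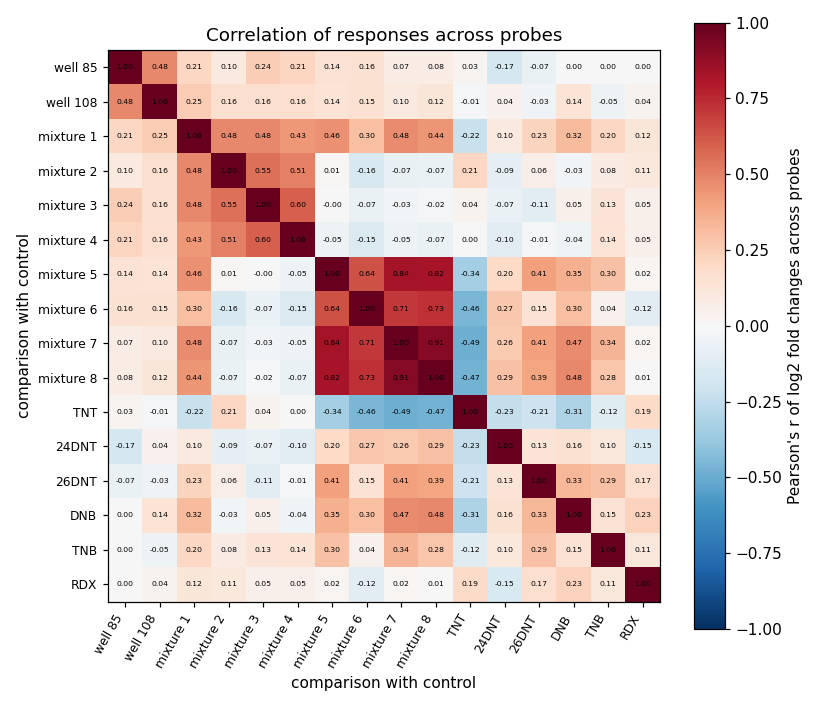
Pearson's r across 4043 probes tested in every exposure between the responses to each pair of comparisons with control, from -1 (blue) to 1 (red). Mixtures 7 and 8, which share controls, reach 0.91, and TNT runs against mixture 7 at -0.49.

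Single probes did recur between exposures with separate controls. DM02535P1 passed upward in well 85, mixtures 5, 7 and 8 and TNB, and DM02984P3 in well 85 and mixtures 1, 5, 7 and 8, and these were the 2 probes called higher in 3 exposures. In 2 or more exposures, 39 probes were called higher and 8 lower. Of the probes higher in well 85, 6 were also higher with TNT (0.658 by independent lists), 4 with TNB (0.681), 3 with mixture 1 (0.0759) and 3 with mixture 4 (0.0664). With the mixtures made to stand for groundwater it shared 2 with mixture 5 (0.0506), 2 with mixture 7 (1.81, adjusted p 1 by Fisher's exact test) and 2 with mixture 8 (0.486, adjusted p 0.318). The 50-nucleotide sequence of DM11208P3 on the array is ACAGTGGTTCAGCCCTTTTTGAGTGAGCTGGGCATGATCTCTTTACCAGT, and that of DM02535P1, with 60 nucleotides, is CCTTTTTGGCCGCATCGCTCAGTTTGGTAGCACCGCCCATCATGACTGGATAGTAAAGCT.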

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

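The control-array brightness tests were fixed before their results were seen, though counts with brightness as a covariate were already known. The tests within groups, with slide as a block, with divided controls, of spike-ins, of the well probes left after leaving out those an exposure brought in, of shared sequence, of an exchange of arrays and of other splits of the arrays were chosen after the results were seen.

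Among 123 groups of values, 10 held 1 array far from the rest, and chance gives about 1 in 20. In mixture 7, replicate 5 had 36.4% of probes well above background against 25.1% to 26.2% in the others. The 75th percentile signal was 54.1 in DNB exposed replicate 3 against 26.7 to 30.6, and 289 in RDX control replicate 3 against 41.6 to 58.6. DM11208P3 lay at -1.32 in mixture 1 replicate 2, where the other 4 arrays lay between 1.86 and 2.51. In the controls of mixtures 1 to 4, replicate 2 stood apart for DM04077P2 at -0.54 and for DM08406P3 at 1.49. In the controls of mixtures 5 to 8, replicate 4 stood apart for DM02984P3 at -3.66 and for DM04369P3 at 2.45, where the other 4 lay between 8.01 and 9.58. DM11495P2 lay at 0.88 in TNT exposed replicate 1 against 6.82 to 7.35 in the others, and DM06036P1 at -0.85 in TNB exposed replicate 1 against 4.14 to 4.36.

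Responses to related chemicals differed by the interaction test in limma in 5 pairs, with 3 probes for 24DNT against 26DNT, 77 for TNT against TNB, 58 for DNB against TNB, 301 for TNT against 24DNT and 23 for TNT against 26DNT. With slide as a block these counts were 0, 0, 27, 3 and 0. Doses in mg/L and control groups differed within each pair as well.

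Mixtures 7 and 8 had the most called probes of the comparisons with control as reported, with DM02535P1 24.2-fold and 21.0-fold higher and most called probes lower. This order depended on the processing. Counts were 3 and 0 under normexp (246 for TNT), 13 and 12 with brightness as a covariate (145 for well 85), 183 and 564 with slide as a block (222 for TNT) and 1297 and 17 without arrays in doubt. Noise of single control arrays used in both comparisons does not account for their likeness. The responses correlated at 0.67 on average, with a lowest value of 0.57, when the 5 controls were divided between the 2 mixtures. A difference common to all 5 controls, such as in brightness, would stay in both parts, so dividing them cannot exclude it. Brightness is open. Slopes on brightness in 34 control arrays of other exposures predicted -18.2% and -14.8% of the median change in mixtures 7 and 8, the opposite sign, which by the criterion written beforehand would argue against brightness. After the within-group result was seen this reading was changed to open. That test assumed that slopes carry over between exposures, and in this set they did not. The signed mean of the called probes fell with brightness within groups, with a negative r in each of the 5, at r -0.82 for mixture 7 and -0.78 for mixture 8 (permutation p 0.00042 and 0.00125 over 100000 resamples). The slope within the groups predicted 29.3% of the mean change in mixture 7 (25.8% to 31.4% with single arrays left out) and 27.3% in mixture 8 (24.0% to 29.2%). With brightness as a covariate the median change fell from 2.43 to 1.76 in mixture 7 (median SE 0.63 and 0.67) and from 2.68 to 1.98 in mixture 8 (median SE 0.66 and 0.67). Of the 620 and 296 called probes 11 in each still passed. The change shrank while its error did not. The covariate took a single degree of freedom from a fit of 22 arrays in 5 groups, which argues against that loss as the reason most calls ended.

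Spike-in signals of mixtures 5 to 8 differed from those of the controls by 0.0549 ± 0.28 (SE, 17 against 5 arrays, exact p 0.862), while brightness differed by -1.16 ± 0.54 (SE, exact p 0.0228). Poor hybridisation or scanning of whole arrays would lower both alike. In mixtures 7 and 8 the spike-ins differed from control by 0.01 ± 0.34 and brightness by -1.52 ± 0.53 (SE, 8 against 5 arrays). The gap between these differences was 1.53 ± 0.40 (SE, exact p 0.00311), which argues against hybridisation or scanning as the whole of the dimness. A lesser part lies within the spread of the spike-ins and stays open. The 4 spike-ins used, of 10, were picked after their signals were seen, for lying in the middle of the range. A smaller or degraded RNA input, which may differ between samples for technical reasons or through toxicity, remains a candidate explanation, and the spike-in difference of 0.0549 does not test it, since spike-ins do not pass through the animals' RNA. An effect of the mixtures themselves also stays open. DM02535P1 passed in mixture 7 with brightness as a covariate.

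The second pattern is the set of 20 probes higher with both TNT and TNB, among them DM12902P2, DM12463P3 and DM06036P1. Their median rise was 3.07 with TNT and 5.17 with TNB. Slopes from control arrays of other exposures predicted -2.67% of the rise with TNT and 0.585% with TNB, which assumes that slopes carry over between exposures. Slopes within the groups, over 8 arrays each, predicted -18.0% and -0.545%. Within the TNT groups the set fell with brightness (r -0.73, permutation p 0.0555), and the TNT exposed arrays were brighter than control by 0.93 log2 units. Brightness would thus lower the set with TNT, which argues against it as the cause of the rise. With brightness as a covariate the median rise was 3.72 with TNT (median SE 0.50 before and 0.59 after) and 5.23 with TNB, and 0 of 20 passed for TNT and 12 of 20 for TNB. Why the TNT calls ended although the rise grew was not tested, and the covariate also takes up a degree of freedom in a fit of 8 arrays. The 20 probes formed 20 families by stretches of 20 nucleotides, so an exact shared stretch of that length does not account for the set. Probes for different parts of the same transcript, or with imperfect matches, would not be joined. Whether the 20 probes measure separate transcripts was therefore not tested. Over 4043 probes, however, the TNT and TNB responses correlated at r -0.12. Of 69 probes called with TNT and tested with TNB, 41 moved the same way, these 20 among them. Of 76 called with TNB and tested with TNT, 60 did. A response common to both trinitro compounds may still underlie the set of 20, though the overlap was 0 to 30 probes under the other settings. In mixtures 5 to 8, of 14 members tested, 1, 0, 0 and 1 were higher, with medians of -0.89 to -1.45. These arrays were dim, by -1.65 and -1.39 log2 units against control in mixtures 7 and 8, where DM12902P2 was measured on 0 of 4 arrays each, so the lower values there were not read as a response. In mixtures 1 to 4, of 20 tested, 12, 17, 18 and 15 were higher, with medians of 0.38 to 1.25 and 0 called. These groups were not tested against each other.

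The third pattern is the set of 14 probes higher in a well and in another exposure, among them DM11208P3, DM02535P1 and DM02984P3. Brightness slopes from other exposures predicted -0.202% of the median rise in well 85, and slopes within the groups -0.661% of the mean rise. With slide as a block 91.1% of the median rise was left (2.30 before and 2.09 after, 14 of 14 higher), and 5 of 14 passed. Both tests argue against brightness and slide as the whole cause. The set was chosen partly by calls in the other exposures, so probes that were in it only through the exposure in question were left out of what follows. Of those left and tested, 7 of 8 lay higher with TNT (median 1.51), 5 of 9 with TNB (0.29), 4 of 6 with DNB (0.99), 3 of 9 with 24DNT (-0.06), 2 of 4 with 26DNT (0.00) and 2 of 6 with RDX (-0.48). In mixtures 1 to 4, which share controls, 9, 10, 11 and 10 of 11 lay higher, with medians of 0.91, 1.03, 1.38 and 0.88. In mixtures 5 to 8, made to stand for field groundwater, 7, 7, 6 and 7 of 13 did, with medians of 0.35, 0.35, -0.07 and 0.00. The sets of mixtures were not tested against each other, and the arrays of mixtures 5 to 8 were dim, with 27.2% to 41.6% of probes well above background on average. The well chemistry is not given, so whether the wells share chemicals with these exposures was not tested.

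Other splits of the arrays into groups of the same sizes were refitted, at most 100 per result. As many probes as the real split came from 1 of 100 splits for well 85 (155 probes, 84 in the highest other split), 1 of 100 for well 108 (9 and 7), 1 of 100 for well 108 vs well 85 (24 and 8), 1 of 100 for mixture 4 (12 and 2), 1 of 35 for TNT (92 and 10) and 1 of 35 for TNB (80 and 3), each a share under 0.05. The real split is counted in each share, so 1 of 35 is the lowest share that 35 splits can give. The counts for TNT and mixture 4 also fell to 0 when single arrays were left out. The share was also under 0.05 for the interactions of TNT and TNB (1 of 100, 77 and 3), DNB and TNB (1 of 100, 58 and 25), TNT and 24DNT (1 of 100, 301 and 6), TNT and 26DNT (1 of 100, 23 and 15) and 24DNT and 26DNT (2 of 100, 3 and 7). Splits of the interactions regrouped exposed and control arrays in both exposures, as if neither chemical had an effect. They therefore do not exclude chance for a difference between chemicals. For mixture 1 (2 of 100, 10 and 31) and mixture 2 (4 of 100, 1 and 2) the share was also under 0.05. None of the shares from splits was corrected for the number of results, so they do not exclude chance for the results as a whole. The single call of mixture 2 was lost in 6 of 9 omissions, so little rests on it.

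For mixtures 5, 7 and 8 the share of splits was also under 0.05, with 3 of 100 for mixture 5 (55 probes, 464 in the highest other split), 1 of 100 for mixture 7 (620 and 612) and 1 of 100 for mixture 8 (296 and 290). Those highest splits point to a structure of the samples. For mixture 5 the split exchanged control replicate 4 with mixture 5 replicate 4, and for mixtures 7 and 8 it put control replicate 4 with the exposed arrays. Control replicate 4 was the dimmest control, with a 75th percentile signal of 15.1, and mixture 5 replicate 4 the brightest of mixture 5, with 53.8. On an axis from the other controls (0) to mixtures 6 to 8 (1), control replicate 4 lay at 0.61, above the other controls (-0.05 to 0.31) and below 3 of the other 4 mixture 5 arrays (1.04 to 1.33). Mixture 5 replicate 4 lay at 0.20 and replicate 2 at 0.26, both within the range of the controls. An exchange of the labels of control replicate 4 and mixture 5 replicate 4 cannot be told apart from an effect of brightness by these values, since control replicate 4 lay between the groups. Without control replicate 4 the counts were 102 for mixture 5, 816 for mixture 7 and 404 for mixture 8. For mixture 1, a split with 31 calls exchanged 2 controls with 2 exposed arrays.

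Chance could not be excluded for 24DNT, where 2 of 35 splits gave as many (3 probes, 11 in the highest other). For the results with a count of 0, every split gave as many, which holds by construction. These were 100 of 100 for mixture 3 (highest other 0), mixture 6 (2), the differences among mixtures 1 to 4 (7) and among mixtures 5 to 8 (2), and 35 of 35 for 26DNT (1), DNB (0) and RDX (4).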

How the results depend on the processing

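Array brightness as a covariate, array weights and the omission of arrays in doubt were chosen after the results were seen, and the other alternatives before. Counts are of probes at adjusted p under 0.05 with limma, and a count is given where it left the range within 1.5 times the reported one. For the changes below, the cause was not tested. The reported counts were 155 for well 85, 9 for well 108, 24 for well 108 vs well 85, 10 for mixture 1, 1 for mixture 2, 0 for mixture 3, 12 for mixture 4, 0 for differences among mixtures 1 to 4, 55 for mixture 5, 0 for mixture 6, 620 for mixture 7, 296 for mixture 8, 0 for differences among mixtures 5 to 8, 92 for TNT, 3 for 24DNT, 0 for 26DNT, 0 for DNB, 80 for TNB, 0 for RDX, 3 for 24DNT vs 26DNT, 77 for TNT vs TNB, 58 for DNB vs TNB, 301 for TNT vs 24DNT and 23 for TNT vs 26DNT.

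Normexp background correction gave 28 for well 85, 1 for differences among mixtures 1 to 4, 3 for mixture 7, 246 for TNT, 70 for 24DNT, 4 for TNB, 12 for 24DNT vs 26DNT, 149 for TNT vs TNB, 2 for DNB vs TNB, 470 for TNT vs 24DNT and 130 for TNT vs 26DNT, and 0 for well 108, well 108 vs well 85, mixture 2, mixture 5 and mixture 8. The split changed with it from 95 higher and 60 lower to 10 and 18 for well 85, from 9 and 1 to 5 and 7 for mixture 1, from 212 and 408 to 3 and 0 for mixture 7, from 3 and 0 to 11 and 59 for 24DNT, from 72 and 8 to 1 and 3 for TNB, from 3 and 0 to 1 and 11 for 24DNT vs 26DNT, from 45 and 32 to 140 and 9 for TNT vs TNB, from 6 and 52 to 0 and 2 for DNB vs TNB, from 227 and 74 to 445 and 25 for TNT vs 24DNT, and from 23 and 0 to 101 and 29 for TNT vs 26DNT. Under normexp the average correlation with mixtures 5 to 8 was 0.53 for well 85 and 0.50 for well 108. That of mixture 1 with the sum of the 6 single chemicals was 0.56. The normexp offset of 50 lay above the 75th percentile signal of every mixture 7 and 8 array (highest 20.2 and 25.6), which shrinks log2 changes there. DM03029P4 in well 108 reversed to 0.46 under normexp, and it was the only named probe to reverse in any setting. Of the named changes, 39 no longer passed under normexp and 18 still did.

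Quantile normalization gave 1 for mixture 1, 20 for mixture 5, 6 for 24DNT and 1 for DNB, and 0 for mixture 2, mixture 4 and TNT vs 26DNT. The deposited value table gave 1 for mixture 1, 9 for mixture 5, 193 for mixture 8, 154 for TNT, 15 for 24DNT, 5 for 24DNT vs 26DNT and 124 for TNT vs TNB, and 0 for mixture 2, mixture 4 and TNT vs 26DNT. With quantile normalization the split was 0 higher and 1 lower for mixture 1, 4 and 16 for mixture 5, 5 and 1 for 24DNT, and 10 and 34 for DNB vs TNB. With the value table it was 8 and 1 for well 108, 3 and 28 for well 108 vs well 85, 0 and 1 for mixture 1, 2 and 7 for mixture 5, 108 and 46 for TNT, 12 and 3 for 24DNT, and 11 and 33 for DNB vs TNB.

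Without the filter on dim probes the counts were 4 for mixture 4, 6 for mixture 5, 150 for mixture 8, 3 for TNT, 1 for 24DNT, 45 for TNB, 10 for RDX, 10 for TNT vs TNB and 189 for TNT vs 24DNT, and 0 for TNT vs 26DNT. With slide as a block they were 32 for well 85, 1 for mixture 5, 183 for mixture 7, 564 for mixture 8, 222 for TNT, 7 for 24DNT, 128 for TNB, 27 for DNB vs TNB and 3 for TNT vs 24DNT, and 0 for well 108, well 108 vs well 85, mixture 1, mixture 2, mixture 4, 24DNT vs 26DNT, TNT vs TNB and TNT vs 26DNT.

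The replicate number as a block gave 3 for well 108, 14 for well 108 vs well 85, 7 for mixture 4, 13 for mixture 5, 171 for mixture 8, 50 for TNB and 10 for TNT vs 24DNT, and 0 for TNT, 24DNT vs 26DNT, TNT vs TNB and TNT vs 26DNT, and 120 for well 85 and 483 for mixture 7. It moved no other count by more than 1.5 times. The mean correlation of deviations between arrays of 1 number ran from -0.04 with 24DNT to 0.08 with 26DNT. Arrays that correlated best with their own number were 5 of 15 for groundwater, 6 of 22 and 3 of 22 for the mixture sets, 6 of 8 for 26DNT (lowest r 0.02), 4 of 8 for TNT, 2 of 8 each for DNB, RDX and TNB, and 0 of 8 for 24DNT. A pairing in 26DNT is not excluded, and its count was 0 with the replicate block as well.

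Brightness as a covariate gave 22 for mixture 1, 18 for mixture 2, 1 for mixture 3, 47 for mixture 4, 1 for mixture 5, 13 for mixture 7, 12 for mixture 8, 33 for TNB, 21 for TNT vs TNB, 41 for TNT vs 24DNT and 51 for TNT vs 26DNT, and 0 for TNT and 24DNT. Array weights gave 551 for well 85, 110 for well 108, 232 for well 108 vs well 85, 62 for mixture 1, 22 for mixture 2, 63 for mixture 3, 50 for mixture 4, 198 for mixture 5, 618 for mixture 6, 2900 for mixture 7, 2466 for mixture 8, 429 for TNT, 9 for 24DNT, 1 for RDX, 136 for TNT vs TNB and 70 for TNT vs 26DNT. Without the 8 arrays in doubt the counts were 30 for mixture 1, 11 for mixture 2, 1 for mixture 3, 50 for mixture 4, 2 for mixture 5, 1297 for mixture 7, 17 for mixture 8, 1 for 26DNT, 13 for 24DNT vs 26DNT and 1 for TNT vs 26DNT.

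With single arrays left out, the count for well 85 ran from 107 to 150. That for well 108 ran from 6 to 14, with 14 without control replicate 1. That for well 108 vs well 85 ran from 11 to 27, with 14 and 14 without well 85 replicates 2 and 4, and 11, 15 and 14 without well 108 replicates 1, 2 and 4. That for mixture 1 ran from 0 to 30, with 5, 1, 5 and 0 without control replicates 1, 2, 3 and 4, and 3, 30, 0 and 5 without exposed replicates 1, 2, 3 and 5. That for mixture 2 ran from 0 to 3, with 3, 0, 0 and 0 without control replicates 1, 2, 4 and 5, and 0, 2, 0 and 0 without exposed replicates 1, 2, 4 and 5. That for mixture 3 stayed at 0. That for mixture 4 ran from 0 to 34, with 2, 3, 0 and 6 without control replicates 2, 3, 4 and 5, and 34, 0 and 0 without exposed replicates 2, 3 and 5. That for differences among mixtures 1 to 4 ran from 0 to 2, with 2 without mixture 4 replicate 2. That for mixture 5 ran from 0 to 388, with 0, 7, 6, 102 and 16 without control replicates 1, 2, 3, 4 and 5, and 5, 215, 0, 388 and 11 without exposed replicates 1, 2, 3, 4 and 5. That for mixture 6 ran from 0 to 1, with 1 without exposed replicate 1. That for mixture 7 ran from 266 to 816, with 281, 286 and 319 without control replicates 1, 3 and 5, and 294, 368 and 266 without exposed replicates 3, 4 and 5. That for mixture 8 ran from 70 to 404, with 86, 157, 70 and 96 without control replicates 1, 2, 3 and 5, and 146, 138 and 70 without exposed replicates 1, 2 and 4. That for differences among mixtures 5 to 8 ran from 0 to 2, with 2 and 2 without mixture 5 replicates 3 and 4, and 1 without mixture 6 replicate 1, and 2 without mixture 8 replicate 3. That for TNT ran from 0 to 443, with 1, 7, 0 and 443 without control replicates 1, 2, 3 and 4, and 1, 6, 0 and 0 without exposed replicates 1, 2, 3 and 4. That for 24DNT ran from 0 to 8, with 1, 0 and 0 without control replicates 2, 3 and 4, and 1, 8, 0 and 0 without exposed replicates 1, 2, 3 and 4. That for 26DNT ran from 0 to 1, with 1 without control replicate 1. That for DNB stayed at 0. That for TNB ran from 19 to 98, with 34, 35, 19 and 33 without control replicates 1, 2, 3 and 4, and 40 and 29 without exposed replicates 2 and 4. That for RDX stayed at 0. That for 24DNT vs 26DNT ran from 0 to 13, with 1 and 0 without 24DNT control replicates 3 and 4, and 0, 0 and 0 without 24DNT exposed replicates 1, 3 and 4, and 13, 0, 1 and 0 without 26DNT control replicates 1, 2, 3 and 4, and 0 and 0 without 26DNT exposed replicates 2 and 3. That for TNT vs TNB ran from 0 to 212, with 8, 33, 0 and 12 without TNB control replicates 1, 2, 3 and 4, and 9 and 22 without TNB exposed replicates 2 and 4, and 30, 14, 2 and 212 without TNT control replicates 1, 2, 3 and 4, and 10, 9, 1 and 17 without TNT exposed replicates 1, 2, 3 and 4. That for DNB vs TNB ran from 29 to 76, with 35 and 33 without DNB exposed replicates 1 and 3, and 30, 33 and 29 without TNB control replicates 1, 2 and 3, and 37 and 30 without TNB exposed replicates 3 and 4. That for TNT vs 24DNT ran from 95 to 637, with 188, 118, 158 and 186 without 24DNT control replicates 1, 2, 3 and 4, and 140 and 140 without 24DNT exposed replicates 1 and 2, and 161, 151 and 637 without TNT control replicates 1, 3 and 4, and 95, 193, 122 and 117 without TNT exposed replicates 1, 2, 3 and 4. That for TNT vs 26DNT ran from 0 to 57, with 1, 35, 0 and 0 without 26DNT control replicates 1, 2, 3 and 4, and 1, 0, 0 and 0 without 26DNT exposed replicates 1, 2, 3 and 4, and 12, 1, 0 and 57 without TNT control replicates 1, 2, 3 and 4, and 1, 0, 0 and 0 without TNT exposed replicates 1, 2, 3 and 4. These name each array whose omission moved a count by more than 1.5 times.

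The planned correlations ran, with single arrays left out, from 0.03 to 0.11 for well 85 against mixtures 5 to 8, from 0.07 to 0.19 for well 108 against mixtures 5 to 8, from -0.04 to 0.07 for mixture 3 against the sum of TNT and 24DNT alone, from 0.10 to 0.31 for mixture 1 against the sum of the 6 single chemicals. Named changes kept their direction in every omission. DM11208P3 in both wells, DM02535P1 in mixtures 7 and 8 and DM12902P2 with TNB also passed in each omission. DM11208P3 in well 85 and DM02535P1 in mixture 7 passed under every other alternative run as well. DM11208P3 in well 108 did not pass under normexp or with slide as a block, and DM02535P1 in mixture 8 and DM12902P2 with TNB did not pass under normexp. Named changes that no longer passed numbered 32 with slide as a block, 23 with the replicate block, 21 without the dim filter, 19 with brightness, 15 with the value table, 14 with quantile normalization, 8 without arrays in doubt and 3 with weights. Depth limits the dim side, and with 27.2% of probes well above background in mixture 8, folds against dim groups are bounds.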

Other observations

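The list lookups and the reading across exposures below were chosen after the results were seen.

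DM02535P1 lay higher than control in all 16 comparisons with control, from 0.28 with 24DNT to 4.60 with mixture 7, and passed in 5 of them. DM05883P1 rose 45.4-fold in well 85 and 10.1-fold in well 108 as fitted, with 3 of 5 control arrays measuring it. The change in well 108 did not pass (adjusted p 0.11, limma). Its change was positive in every comparison in which it was tested. DM12902P2, the probe with the largest rise with TNB, lay at least 3.86-fold lower in mixture 7 and at least 3.92-fold lower in mixture 8, where 0 of 4 arrays each and 5 of 5 control arrays measured it (adjusted p 0.0092 and 0.0116, limma). Both mixtures held TNB, at 0.144 and 0.159 mg/L against 0.386 alone. Their arrays were dim, by -1.65 and -1.39 log2 units against control, so these lower values were not read as a response. The control level of DM12902P2 ran from -1.39 with RDX to 3.54 with mixtures 1 to 4.

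Each of 10 lists of probes called in 1 comparison was looked up in exposures with other controls, in 133 lookups. With camera's preset correlation of 0.01, 81 passed, and with the correlation estimated from the data 0 did. The 95 probes higher in well 85 lay higher in mixture 3 for 76 of 86 tested, with a median of 0.58. The adjusted p of that lookup was 7.26e-18 with the preset and 0.14 with the estimated correlation (0.176).

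The response to TNT ran against that to mixtures 5 to 8, at r -0.34 to -0.49 across 4043 probes, while the DNB response correlated with mixtures 7 and 8 at 0.47 and 0.48. These pairs have separate controls. The TNT exposed arrays were brighter than their controls by 0.93 log2 units, and those of mixtures 7 and 8 dimmer by 1.65 and 1.39, and whether brightness accounts for the opposite signs was not tested.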
